A study of Mus musculus with 80 samples.

How the data were processed

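Liver RNA was measured in 20 female Balb-C mice aged 10 to 12 weeks. The mice had received PFESA-BP2 by gavage on 7 days, at 0, 0.03, 0.3, 3.0 or 6.0 mg/kg-day, with 4 mice per dose. Each mouse gave 1 library, run over 4 lanes of an Illumina NextSeq 500, so the labels list 80 lane samples. The control titles name DMSO while the design text names deionized water, and the vehicle was taken as unsettled. The study title speaks of targeted sequencing, while the table holds 22103 gene rows. No list of targets was used here.

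The deposited table gives expected counts per gene, with 1 column per library and 58.0% of the values whole. That unit was read from the values themselves, which never fell below 0 and whose column totals differed. The submitters' processing notes name Partek and the genome build GRCm38.p5. The aligner, the counting method, the annotation and their versions are not given in the sources used here, nor is whether counting used strand. The smallest row total in the deposited table was 10 counts, and 0 rows were at 0 in every library. Of the rows, 21 carried names in the form of dates, of which 2 names occurred more than once. These rows were kept as rows of their own and are not named in the text. A gene symbol of the GENCODE M21 annotation of GRCm38 was found for 20992 rows (95.0%), and coordinates are given from that annotation.

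The expected counts were rounded to whole numbers. Total counts per library ranged from 13086779 to 21467012. Rows with low counts were left out with edgeR's filterByExpr on the dose groups, which kept 15197 rows and left out 6906. Libraries were scaled with TMM factors, and levels are given as CPM (edgeR's cpm function) on the scaled totals. Means are given with the SD over 4 mice per group, and log2 fold changes with an approximate standard error (SE). This SE is the absolute change divided by the square root of the F value of edgeR's quasi-likelihood test.

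The test for every gene was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) in a single fit of all 20 mice with a mean per group and 15 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 counted as passing. The biological coefficient of variation was 0.219. Each dose was compared with the control, and 6.0 with 3.0 mg/kg-day. A joint test of the dose terms asked for a difference at any dose. A separate fit with a slope on the dose rank asked for a trend. Every adjusted p for a gene in the text comes from these fits unless another tool is named.

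Gene lists for 34 liver processes and for the markers of cell types were written before the data were examined. Camera (limma 3.58.1) tested whether a list moved relative to the other genes, for lists with 5 or more measured members, which left 9 of the marker lists. Its inter-gene correlation was preset at 0.01, and each result was repeated with a correlation estimated from the data. Adjustment was over the lists tested in a comparison. The number of members that passed is given over all genes tested and also adjusted over the list alone. The lists came from general knowledge and not from these mice, and some genes are in more than 1 list.

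The genes named in the text were chosen by rules fixed before the data were examined. For each dose these were the 10 largest rises and 10 largest falls among genes that passed, had a mean of 10 CPM or more, and had every treated mouse on the same side of every control mouse. For each list, the 4 members with the smallest adjusted p at 6.0 mg/kg-day were added. A fixed set of sentinel genes was added whatever their result, and so were the 5 largest rises and 5 largest falls of the trend and of 6.0 against 3.0 mg/kg-day. For the trend, separation from the controls was required at 6.0 mg/kg-day, a detail settled after the rules were fixed. The text names only part of the genes these rules give, and reports some of them also at doses for which the rules did not give them. Other genes are named as chosen after their values were seen.

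The fits were tested on simulated counts, drawn with the real library sizes, the control means and the spread fitted per gene. In the groups in place of each dose, in rising order, edgeR tested 14819 genes and recovered 51, 58, 50 and 47 of 100 genes changed by 2-fold. It recovered 18, 13, 10 and 13 of 100 genes changed by 1.5-fold and called 7, 1, 2 and 3 unchanged genes. DESeq2 recovered 64, 65, 59 and 54 of the genes changed by 2-fold and called 25, 13, 18 and 11 unchanged genes. The trend recovered 63 of 100 genes that moved by 2-fold over the doses and 28 of 100 that moved by 1.5-fold, with 6 unchanged genes called. The joint test recovered 342 of 820 changed genes and called 20 unchanged genes. A list of 20 genes raised together had a camera adjusted p of 2.61e-52, and 0 of 30 unchanged lists were called. The simulated genes were drawn independently of each other, so false calls of lists under correlation between genes were not tested. No simulated difference was placed between 6.0 and 3.0 mg/kg-day.

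Comparisons that share the control mice were set against 20 simulations in which a control group and a pair of unchanged groups were all drawn from the same means. An earlier form of this simulation drew only the unchanged groups, around the observed mean of the real controls. It left out the chance deviation that the comparisons share and was replaced. The control mice were also split 2 and 2, in 6 ways, with a different pair for each dose.

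Alternatives fixed before the data were examined were RLE factors, total counts without scaling factors, no low-count filter, a mean of 10 CPM or more, the sequencing sample number as a covariate, and the compared groups fitted alone. Others were the trend on dose or on log10 dose, limma-voom, DESeq2 1.42.0 with its own size factors, and each mouse left out in turn. The alternatives for several rows per gene, for a column per lane and for a pseudocount had no object in this table. A pair of alternatives was added after the data were seen: a term for 5 libraries that stood apart from the rest, and a fit without them. Dose groups share no replicate numbers, so no pairing was modelled. Figures were drawn with matplotlib 3.10.9.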

Results

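Liver RNA was sequenced from 20 female Balb-C mice given PFESA-BP2 by gavage on 7 days. PFESA-BP2, also called Nafion byproduct 2, is a perfluoroalkyl ether sulfonic acid. The groups received 0 (control), 0.03, 0.3, 3.0 or 6.0 mg/kg-day, with 4 mice and 4 libraries in each. Total counts per library ranged from 13086779 to 21467012. Group means, in M counts, were 17.5, 17.8, 19.7, 18.2 and 18.2 in order of dose. After the filter on low counts 15197 genes were tested. Levels are in CPM, the counts scaled to a common library total, with the SD over 4 mice, and changes are log2 fold changes with their SE. A gene is said to have risen or fallen where its adjusted p from edgeR's quasi-likelihood test was under 0.05.

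Within the groups, 5 libraries stood apart from the other 15, namely libraries 3, 11, 15, 19 and 23, of which each group held 1. Their distance showed on the first component of the variation left within groups, which held 61.2% of it. Their scores were 0.26 or higher, and those of the other libraries were -0.016 or lower. A fit with a term for these libraries found 3789 genes higher and 3830 lower in them. Since each group held 1 such library, they added to the spread within every group. Counts of genes are therefore given also with a term for these libraries and without them, both chosen after the data were seen.

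**Figure D1:**
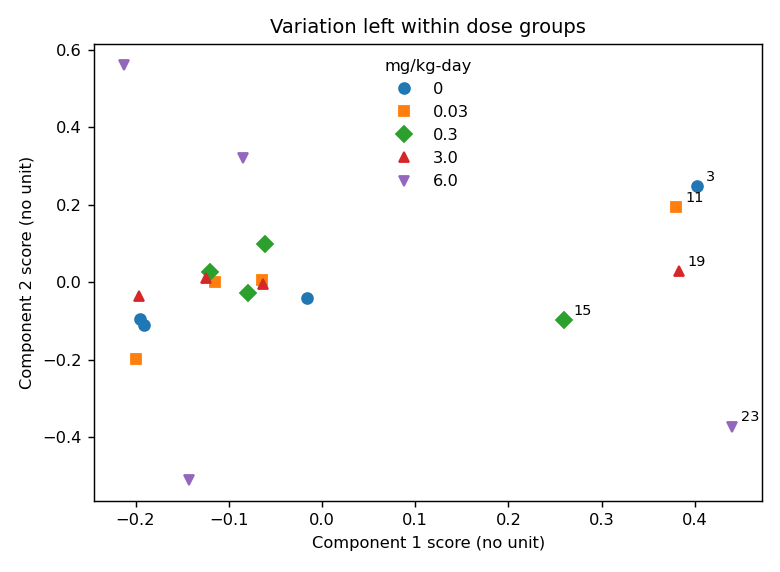
Scores of the 20 libraries on the first (x axis) and second (y axis) component of the variation within dose groups, without unit, with symbols for the dose in mg/kg-day. The 5 numbered libraries have scores of 0.26 or higher on the first component.

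The first comparison asked whether the lowest dose, 0.03 mg/kg-day, changed liver transcripts. By edgeR 0 genes passed, and 565 had an unadjusted p under 0.05. The count was 1 with RLE factors, 1 by limma-voom and 11 by DESeq2. With a term for the libraries apart it was 13, and without those libraries it was 2. All 4 treated mice lay on the same side of all controls for 3.3% of genes, where chance gives 2.86%. Camera called 7 of 34 process lists, with 4 up and 3 down. The PXR (pregnane X receptor) targets had a median change of 0.23 and an adjusted p of 0.000118. None of these 7 process lists was called with an estimated correlation. Of 9 lists of cell type markers 1 was called, that of sinusoidal endothelium, with a median of 0.19 (0.000183; 0.0405 with an estimated correlation), and 0 of its 14 members passed by edgeR.

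At 0.3 mg/kg-day 44 genes passed, of which 21 rose and 23 fell. With a term for the libraries apart the count was 306, and without them it was 158. Single mice weighed on the count. It was 14, 13 and 24 without control libraries 1, 2 and 3, and 17, 16 and 12 without libraries 14, 15 and 16 of this dose. For 6.7% of genes the groups did not overlap, where chance gives 2.86%.

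The genes that rose at 0.3 mg/kg-day included cytochrome P450 genes used as markers of the nuclear receptor CAR (constitutive androstane receptor). Cyp2c55 (chromosome 19, 39007019 to 39042693, GENCODE M21 on GRCm38) had 2.75 ± 0.768 CPM in controls and 29.97 ± 5.96 CPM at this dose. Its change was 3.44 ± 0.286 (adjusted p = 2.36e-06). Cyp2b10 (chromosome 7, 25897620 to 25926624) went from 86.8 ± 23.6 to 582 ± 172 CPM, a change of 2.75 (adjusted p = 5.12e-06). Cyp2c29, of the same enzyme class, changed by 1.69 (adjusted p = 5.12e-06). Members of the Cyp2c and Cyp2b families are similar in sequence, and how reads were divided among them is not given in the sources used here. Abcc4, an efflux transporter, rose by 1.24 (adjusted p = 0.0244), and the carboxylesterase gene Ces2c by 1.00 (adjusted p = 0.0234). Leaving out a mouse ended the call of Abcc4 in 6 of 8 cases (libraries 1, 2, 3, 14, 15 and 16) and that of Ces2c in 4 (libraries 1, 2, 15 and 16), with adjusted p up to 0.142 and 0.0996.

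The falls at 0.3 mg/kg-day included genes regulated by growth hormone or expressed more in female than in male liver. Socs2, a feedback inhibitor of growth hormone signalling, fell by 2.00 (adjusted p = 0.0142), from 56.4 ± 21.1 to 14.1 ± 5.5 CPM. Serpina4-ps1, a pseudogene, fell by 4.26 (adjusted p = 0.000482), and Cyp2c69, a female-biased gene, by 2.49 (adjusted p = 0.00395). Vnn1, a pantetheinase gene and PPARA (peroxisome proliferator-activated receptor alpha) target, had an adjusted p of 0.0427 and was lower, at 16.4 ± 4.3 CPM against 38.0 ± 8.64 CPM. Cdkn1a, which encodes a cell cycle inhibitor, fell by 1.60 (adjusted p = 0.0479), at only 2.02 ± 0.618 CPM in controls. The rules for named genes give Cdkn1a at 6.0 mg/kg-day only, and its result at 0.3 mg/kg-day was chosen after it was seen. Leaving out a mouse ended the call of Socs2 in 4 of 8 cases (libraries 1, 14, 15 and 16), with adjusted p up to 0.0856. It ended those of Vnn1 and Cdkn1a in 7 (libraries 1, 2, 3, 13, 14, 15 and 16), with adjusted p up to 0.172 and 0.206, while the changes stayed within -1.35 to -1.09 for Vnn1 and -1.73 to -1.36 for Cdkn1a in all 8 fits. Without the 5 libraries apart neither passed (0.0539 and 0.0534), with changes of -1.11 and -1.62. With the term for those libraries all 44 genes still passed in the same direction.

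Camera called 16 of 34 process lists at 0.3 mg/kg-day, and 4 were also called with an estimated correlation. Of 21 CAR targets 6 rose, and 14 rose adjusted over the list alone, with a median of 0.69 (adjusted p = 1.38e-43; 0.000304 with an estimated correlation). Of 12 PXR targets 3 rose, and 9 rose adjusted over the list alone (adjusted p = 0.00394 with an estimated correlation). Ketogenesis, with a median of -0.32, and the genes of growth hormone and STAT5 signalling, with a median of -0.17, were called down with estimated correlations at 0.0474 and 0.0427. Adjusted over the list alone, 1 ketogenesis gene and 3 genes of growth hormone signalling fell. The female-biased list was called down with the preset correlation (3.36e-06), but its adjusted p was 0.114 with an estimated correlation. Of 9 marker lists 3 were called, sinusoidal endothelium up and Kupffer and erythroid cells down, and 0 with an estimated correlation (0.0663, 0.654 and 0.333).

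At 3.0 mg/kg-day 701 genes passed, of which 483 rose and 218 fell. The count was 1393 with a term for the libraries apart and 854 without them. It was 451 without library 20. For 10.5% of genes the groups did not overlap, where chance gives 2.86%.

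Cyp2c55 reached 344 ± 143 CPM at 3.0 mg/kg-day, a change of 6.96 ± 0.323 (adjusted p = 5.07e-11). Cyp3a11, a PXR target, went from 5597 ± 1870 CPM in controls to 38470 ± 12600 CPM, a change of 2.78 (adjusted p = 2.33e-06), while at 0.3 mg/kg-day it had not passed (adjusted p = 0.0983). Gstm3, a glutathione transferase gene, rose by 4.95. Cyp4a14, a fatty acid hydroxylase gene and PPARA target, rose by 3.09 (adjusted p = 3.98e-06). Top2a, a topoisomerase of dividing cells, rose by 2.57 (adjusted p = 0.000155), from 2.96 ± 0.253 to 17.6 ± 4.84 CPM. Igf1, the liver's main growth hormone product, fell by 0.92 (adjusted p = 0.00135).

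Camera called 21 process lists at 3.0 mg/kg-day, 14 up and 7 down, and 11 were also called with an estimated correlation. Of 36 proliferation genes 28 rose, and 34 rose adjusted over the list alone, with a median of 2.38 (0.000231 with an estimated correlation). CAR targets had 18 of 21 members higher, with a median of 1.63 (4.88e-06 with an estimated correlation). Of 27 genes of phase II conjugation 14 rose, and 18 rose and 1 fell adjusted over the list alone. Of 22 NRF2 targets 11 rose, of 10 genes of omega oxidation 6, and of 25 genes of cholesterol synthesis 10. Adjusted over the list alone these counts of rises were 13, 8 and 20, with 2 falls in omega oxidation. The female-biased list had 4 genes higher and 12 lower, with a median of -0.90 (0.0166 with an estimated correlation). Of 9 marker lists 2 were called, both down, those of hepatocytes (0.0543 with an estimated correlation) and of stellate cells (0.416).

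At 6.0 mg/kg-day 3405 genes passed, of which 1707 rose and 1698 fell, and 1182 had changed by 2-fold or more. The count was 5639 with a term for the libraries apart and 5228 without them. All 3405 genes passed with the term, and 3198 without those libraries. With only this group and the controls in the fit the count was 1725. For 18.5% of genes the groups did not overlap, where chance gives 2.86%.

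**Figure D2:**
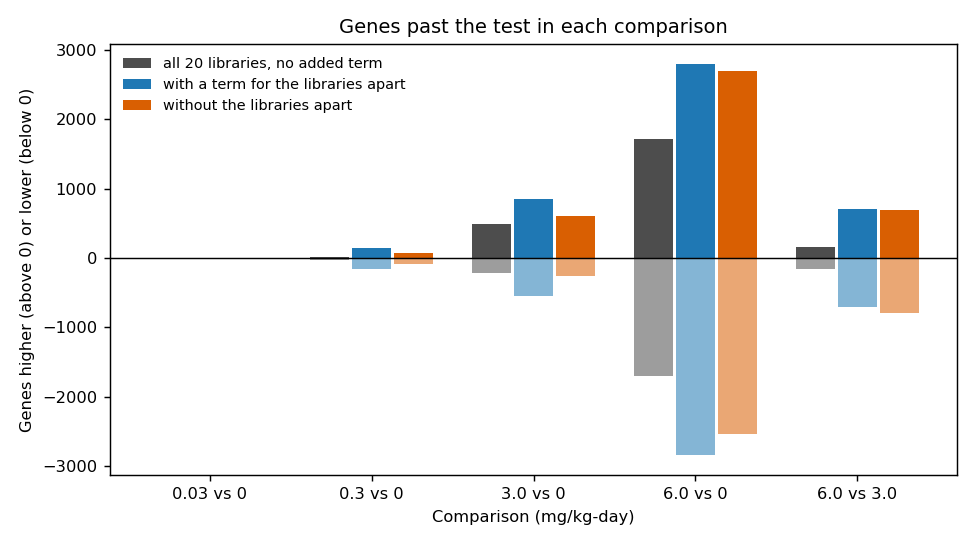
Number of genes (y axis) that were higher (dark bars, above 0) or lower (pale bars, below 0) in each comparison in mg/kg-day (x axis), with colours for the fit of all libraries, with a term for the 5 libraries apart and without them. In the fit of all libraries at 6.0 mg/kg-day 1707 genes were higher and 1698 lower.

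Cyp2c55 was at 645 ± 72.2 CPM at 6.0 mg/kg-day, a change of 7.86 ± 0.334 (adjusted p = 9.44e-12). Cyp2b10 was at 2245 ± 334 CPM, a change of 4.69 (adjusted p = 9.89e-10), and Cyp3a11 at 64360 ± 13000 CPM, a change of 3.52 (adjusted p = 4.06e-08). Cyp4a14 went from 132.6 CPM in controls to 2869 ± 384 CPM, a change of 4.44 (adjusted p = 2.25e-08). The male-biased gene Cyp4a12a went from 1.39 ± 0.774 to 339 ± 145 CPM, a change of 7.89. Counts of the Cyp3a, Cyp4a and Gstm families carry the same uncertainty about similar sequences as those of Cyp2c. Ehhadh, a gene of peroxisomal fatty acid oxidation, rose by 1.62 (adjusted p = 1.95e-07). Vnn1, lower at 0.3 mg/kg-day, was higher by 1.83 (adjusted p = 1.89e-05), and Cdkn1a was higher by 1.97 (adjusted p = 4.81e-05).

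**Figure D3:**
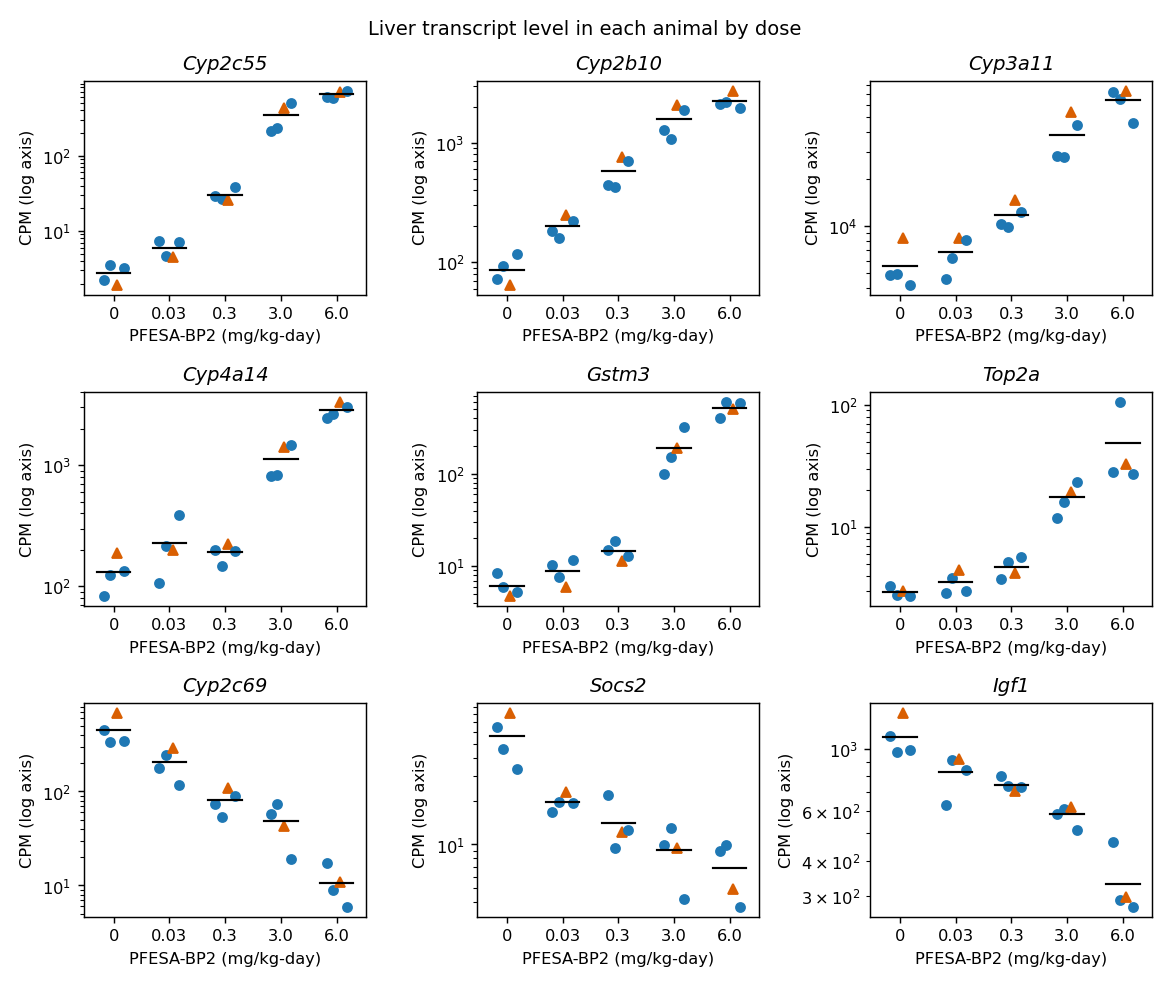
CPM on a log axis (y) of named genes in each mouse, by dose of PFESA-BP2 in mg/kg-day (x), with orange triangles for the 5 libraries apart, circles for the others and bars for group means. Cyp2c55 has a mean of 2.75 CPM in controls and 645 CPM at 6.0 mg/kg-day.

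Top2a was at 48.5 ± 38.1 CPM at 6.0 mg/kg-day, a change of 4.03 (adjusted p = 2.24e-07), with 105.5 CPM in library 22. With each mouse left out in turn its change ran from 3.31 to 4.23, and it passed in all 8 fits. Of 36 proliferation genes 35 rose, with a median of 3.28 (8.15e-63; 0.000943 with an estimated correlation), among them Cdc20 by 4.80 and Prc1 by 4.24. Without library 22 the median was 3.12, and 35 passed. Ccnd1, a cyclin gene, did not pass (-0.04, adjusted p = 0.923). Of 18 p53 targets 9 rose, with a median of 0.64 (0.00843 with an estimated correlation), including Gdf15 by 2.72.

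Of 21 CAR targets 19 rose and 1 fell at 6.0 mg/kg-day, with a median of 2.25 and an adjusted p of 5.12e-05 with an estimated correlation. Of 12 PXR targets 11 rose, and 12 rose adjusted over the list alone. Of 27 phase II genes 22 rose, among them Gsta2 by 3.47, and 1 fell. Of 22 NRF2 targets 17 rose, among them Gstm3 by 6.40, Ugdh by 2.71 and Nqo1 by 1.41 (adjusted p = 0.000556). Gstm3 is also in the CAR and phase II lists. Of the 24 genes of the NRF2 list, 9 are in another list, so these counts are not separate responses. Of 25 cholesterol synthesis genes 19 rose and 1 fell (0.0496 with an estimated correlation), with Idi1 higher by 1.39 and Sqle by 1.41. Adjusted over the list alone, 20 cholesterol synthesis genes rose and 1 NRF2 target fell, and the CAR and phase II counts were the same. Of 8 AhR (aryl hydrocarbon receptor) targets 5 rose and 2 fell, and the list was not called (adjusted p = 0.341). Cyp1a1 rose by 5.35 (adjusted p = 0.000115) to 44.8 ± 68.2 CPM, of which library 22 had 146.7 CPM. Without library 22 its change was 3.30 (adjusted p = 4.18e-05).

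Lists of fatty acid use were called up at 6.0 mg/kg-day, also with estimated correlations. Of 32 genes of peroxisomal oxidation 14 rose and 4 fell (0.0496), of 18 genes of mitochondrial oxidation 9 rose and 1 fell (0.0496), and of 25 other PPARA targets 10 rose and 1 fell (0.045). Of 10 genes of omega oxidation 8 rose and 2 fell (0.00552). Adjusted over the list alone, 10 genes of mitochondrial oxidation and 12 other PPARA targets rose and 1 and 2 fell, and the other counts were the same. Acot1 rose by 2.39 and Cd36, a fatty acid transporter, by 1.83, while Cpt1a, of mitochondrial fatty acid entry, fell by 0.59 (adjusted p = 0.00296). Fabp1, of fatty acid binding (adjusted p = 0.179), and the hormone gene Fgf21 (0.0835) did not pass, and the ketogenesis list was not called (adjusted p = 0.985).

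Of 23 female-biased genes 15 fell and 5 rose at 6.0 mg/kg-day, with a median of -1.51 (0.00513 with an estimated correlation). Cyp2c69 fell by 5.40, to 10.8 ± 4.75 CPM from 454 ± 162 CPM. Of 10 genes of growth hormone and STAT5 signalling 8 fell (0.00135 with an estimated correlation), with Socs2 lower by a log2 change of -3.04 and Igf1 of -1.74. This list holds parts of the pathway, such as Ghr, Stat5a and Stat5b, as well as its targets. Mup20, a male-biased gene of the Mup family, rose by 2.48. The male-biased list had 7 genes higher and 4 lower and was called up (0.000628), but not with an estimated correlation (0.126). Genes of hepatocytes near the central vein had 12 of 16 members lower and 1 higher (0.00324 with an estimated correlation), with Glul at -1.52 and Slc1a2 at -2.53. Genes of hepatocytes near the portal vein had 9 of 13 lower and 1 higher (0.0365 with an estimated correlation). Adjusted over the list alone, 16 female-biased genes and 9 genes of growth hormone signalling fell. In the same way, 1 gene of growth hormone signalling and 10 male-biased genes rose, and the counts near both veins were the same.

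Of the 23 process lists called at 6.0 mg/kg-day, 15 were also called with an estimated correlation. The others included the proteasome, with 21 genes higher (0.0834 with an estimated correlation), complement with 10 lower (0.0834) and coagulation with 10 lower and 1 higher (0.101). Amino acid metabolism had 11 lower and 1 higher (0.208), the circadian clock 7 lower (0.208), glucose metabolism 8 lower and 3 higher of 14 (0.0834) and lipogenesis 7 higher and 3 lower (0.508). Of the genes in these lists, Pck1 fell by 1.83, F11 by 1.51 and C9 by 1.84, and Elovl6 rose by 1.79. Adjusted over the list alone, 23 proteasome and 9 lipogenesis genes were higher, and 13 complement, 12 coagulation, 12 amino acid and 9 glucose genes were lower. The lists of bile acids (0.473), transporters (0.473), lipoproteins (0.136), acute phase (0.679), ER stress (0.988), interferon (0.442), heme and iron (0.473), respiration (0.1) and stress (0.341) were not called. Respiration was called up with the term for the libraries apart (0.0201, with 11 of 29 genes higher) and without them (0.0202, with 10 higher), against 2 higher in the fit of all libraries. Lipogenesis was not called without them (0.462). For acute phase the median was lower while camera's direction was up.

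**Figure D4:**
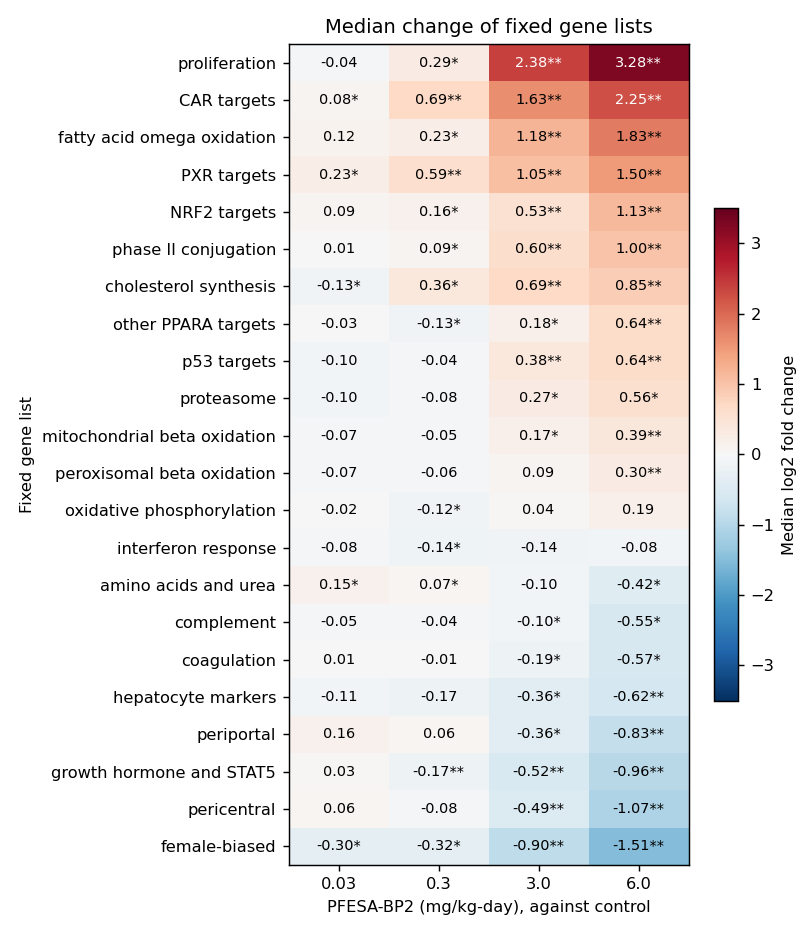
Median log2 fold change of each gene list (y axis) at each dose against control in mg/kg-day (x axis), where * marks a camera adjusted p under 0.05 and ** marks lists called also with an estimated correlation. The proliferation list has a median of 2.38 at 3.0 mg/kg-day and 3.28 at 6.0 mg/kg-day.

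Of 9 lists of cell type markers, 2 were called at 6.0 mg/kg-day, both down. The hepatocyte markers had a median of -0.62 (0.000565; 0.0107 with an estimated correlation), with Alb, the albumin gene, lower by a log2 change of -0.78 (adjusted p = 0.00387). The other lists were not called, namely those of Kupffer cells (0.836), T and NK cells (0.836), B cells (0.991), dendritic cells (0.836), sinusoidal endothelium (0.836), cholangiocytes (0.713) and erythroid cells (0.488). Markers of neutrophils and monocytes had 4 measured members, and those of adipocytes, pancreatic acini and skeletal muscle 1 each, so these were not tested. For the Kupffer cell and B cell lists the median and camera's direction differed in sign. The stellate cell markers had a median of -0.51 (0.042; 0.507 with an estimated correlation), and were not called with the term for the libraries apart (0.0792) or without them (0.147). Lck, a T cell kinase gene, rose by 3.99 (adjusted p = 0.0039) at a mean of 24.2 ± 42.4 CPM, but library 22 alone held 87.6 CPM. Without library 22 its change was 1.01 (adjusted p = 0.142).

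**Figure D5:**
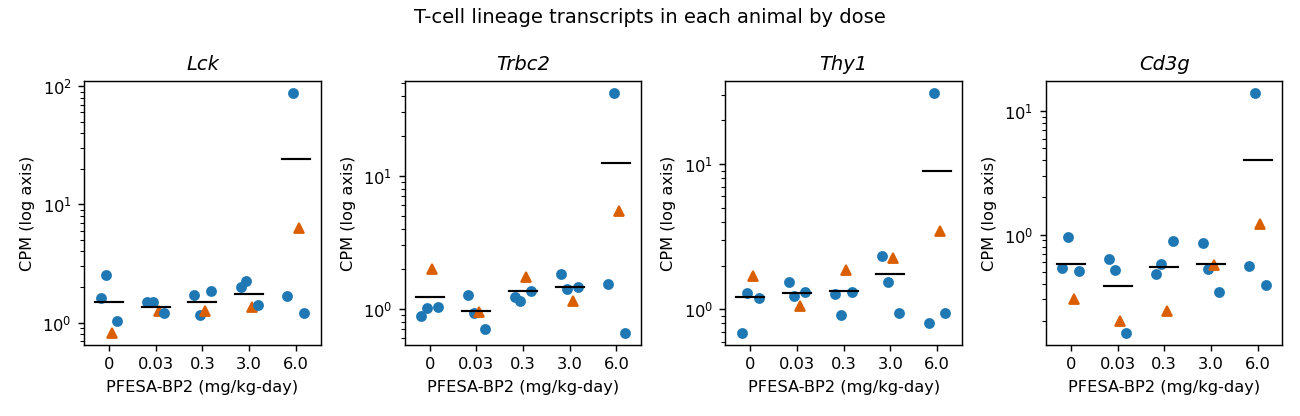
CPM on a log axis (y) of 4 T cell genes in each mouse by dose in mg/kg-day (x), with orange triangles for the 5 libraries apart, circles for the others and bars for group means. Library 22 at 6.0 mg/kg-day has 87.6 CPM of Lck, and library 23 has the next highest level, 6.27 CPM.

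The comparison of 6.0 with 3.0 mg/kg-day asked whether the top dose added to the next one. In the fit of all 5 groups 318 genes passed, of which 157 were higher and 161 lower. With only these 2 groups in the fit edgeR called 0 genes, while 1575 had an unadjusted p under 0.05. DESeq2 called 649 genes. The count was 1400 with a term for the libraries apart and 1476 without them. It was 110 without library 17, 133 without library 18, 126 without library 22 and 969 without library 23. Cyp4a12a was higher by 2.95 (adjusted p = 0.000624). Camera called 25 lists, 13 of them with an estimated correlation, including NRF2 targets (0.00767), proliferation (0.0177) and other PPARA targets (0.0209) up.

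A trend over the dose rank passed for 4013 genes, of which 2076 rose and 1937 fell. The joint test passed for 3255 genes. With the term for the libraries apart these counts were 5824 and 6035, and without those libraries 4966 and 5523. The first dose at which a gene passed was 0.3 mg/kg-day for 44 genes, 3.0 for 668 and 6.0 for 2712. Of the 44 genes, 36 also passed in the same direction at 6.0 mg/kg-day, while Vnn1 and Cdkn1a passed in the other direction.

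Because every dose was set against the same 4 controls, the comparisons share chance values. In 20 simulations of unchanged groups, the correlation of log2 changes across genes had a median of 0.502 and a covariance of 0.042, with 0 genes called in both. The simulations drew genes independently and held no libraries apart, so their ranges may be too narrow for the real data. A value outside them therefore does not show a shared effect of the doses. For 0.03 and 0.3 mg/kg-day the correlation was 0.651 and the covariance 0.0638, both above the simulated maxima of 0.522 and 0.0471, and with the controls split the correlation ran from -0.111 to 0.159. For 0.03 and 6.0 mg/kg-day the correlation was 0.182, below the simulated range, and the covariance 0.0393, within it (0.0386 to 0.0471), with correlations of -0.176 to 0.04 with the controls split. For 0.3 and 3.0 mg/kg-day the correlation was 0.48, which lay within the simulated range of 0.459 to 0.522, and the covariance was 0.0857. For 0.3 and 6.0 mg/kg-day the correlation was 0.34, below that range, and the covariance 0.0918. The comparisons at 0.3 and 3.0 mg/kg-day shared 15 genes higher and 17 lower, where independent lists would share 0.67 and 0.33. With the controls split, 7 to 17 genes were shared and the correlation ran from -0.026 to 0.236. For the pair of highest doses the correlation was 0.867 and the covariance 0.3405. They shared 472 genes higher and 215 lower, where independent lists would share 54.25 and 24.36. With the controls split, 304 to 432 genes were shared and the correlation ran from 0.462 to 0.661. Genes are not independent replicates, so these correlations carry no p-value. In every split of the controls, the control library apart served for either dose of a pair and never for both. Its shift then entered the changes of that pair with opposite signs, which can lower their correlation. Fewer controls per dose can also lower the number of genes shared. Values with the controls split therefore do not isolate the effect of shared controls.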

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

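Among the tests of this part, those of library size and the standard error in the libraries apart, all of library 22, and those of the 5 libraries and of other cell types for proliferation, and the splits by libraries apart and by treated mice on each side were chosen after the result was seen.

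Of 105 groups of mice, over 21 measures, 6 (5.7%) held a library far from the other 3, and chance alone gives such a value in about 1 of 20 groups. Library 22 at 6.0 mg/kg-day had 105.5 CPM of Top2a, 146.7 CPM of Cyp1a1 and 87.64 CPM of Lck, each above the other 3 mice. Library 21 at that dose had 465.9 CPM of Igf1, above the others. Library 11 at 0.03 mg/kg-day was below the others for Mup20 (14.25 CPM), and it is one of the libraries apart. Control library 2 had a median of 1.16 log2 CPM over the proliferation list, below the other controls.

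The 5 libraries apart, 1 in each group, differed from the other 15 with transcript length: Spearman's rho of the shift with length was 0.48 across 14710 genes, which are not independent. The median shift was -0.38 for the shortest and 0.28 for the longest of 4 equal groups of genes by length. The total of the library apart lay between those of the others in 3 groups, which argues against library size. GC content (rho -0.19), clock phase at collection (difference of 0.25 between the arms of the clock) and cells of another type stay open. Median shifts of marker lists with 5 or more measured members ran from -0.92 (T and NK cells) to 0.24 (6 B cell markers, standard error 0.11). A candidate explanation is a difference in RNA or library preparation with a length bias, but no batch is given in the labels.

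In library 22, 4 of 9 measured T and NK cell markers had their highest level of all libraries, as did Thy1, Trbc2, Tcf7, Dntt, Ptprc, Coro1a, Cd79a and Ighm. The median of the T and NK cell list was 1.99 log2 CPM in library 22, against 0.38 to 0.97 in the other libraries. The Kupffer cell list was highest there too (5.01 against up to 4.5 log2 CPM), while the B cell list (1.09) lay within the others. Of the T and NK cell markers, Cd4, Ncr1, Prf1, Il2rb and Ccl5 were not highest there. Cells of another type in the sample therefore stay open. Over the 10 genes at least 5 times above every other library, the medians of 2 of the other 3 mice at 6.0 mg/kg-day lay above every control, as did libraries 9, 13, 16 and 17 of lower doses, while library 24 lay below. Library 23 had 8 of the 10 above every control, and libraries of lower doses at most 3. These genes were picked for their level in library 22 and include Psat1, Gm7901 and the AhR target Cyp1a1. Cyp1a1 rose at 6.0 mg/kg-day also without that library. Over the T and NK cell list, 0 of the other mice at this dose had a median above every control. Without library 22 the median change of that list was -0.42. Since these values go both ways, the dose stays open. Without library 22 Dntt was higher at 6.0 mg/kg-day by 1.35 (adjusted p = 0.00127), while Tcf7 fell by 1.03 (0.0215). A swap with a control mouse is argued against, since library 22 lay nearer the other mice of its dose than the controls at 93.2% of the genes called without it. The test compared only these groups, so it cannot tell of a swap with a mouse of another dose.

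The rise of the proliferation list at 6.0 mg/kg-day did not rest on library 22, without which 35 members passed, nor on the 5 libraries apart, without which 35 of 36 passed. Medians of the marker lists of other cells reached 1.26, for 4 neutrophil and monocyte markers, but were -0.51 for stellate and -0.92 for erythroid cells, so a larger share of other cell types, above all of a single type, stays open. Much of the 1.26 came from library 22: without it that median was 0.24, and the highest was 0.99, of a single adipocyte marker. This did not hold for each marker: S100a8, 1 of the 4, was higher at 6.0 mg/kg-day by 3.29 also without library 22 (edgeR adjusted p = 8.07e-06). Its level was low, at 0.07 to 4.73 CPM in the other libraries. The median of the proliferation list lay above every control in 4 mice at 6.0, 4 at 3.0 and 4 at 0.3 mg/kg-day. At 0.3 mg/kg-day the distance was small, with 1.32 to 1.55 log2 CPM against up to 1.3 in controls. Library 10 at 0.03 mg/kg-day also lay above every control, at 1.46. Which cells divided was not measured.

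The other splits of the same mice show how often a chance division gives as much. Of 35 splits, 1 (the real one) gave as many genes at 0.3 (44, highest other 1), at 3.0 (701, highest other 0) and at 6.0 mg/kg-day (3405, highest other 1610). The same held for 6.0 against 3.0 mg/kg-day (318, highest other 7). Over all splits these shares lie under 0.05, which argues against chance, but 1 of 35 is the smallest share possible. The shares were not adjusted for the number of such tests. The split with 1610 genes set libraries 21, 22, 24 and 1 against a side with both libraries apart, 3 and 23, so it held their contrast as well as that of dose. Of the 35 splits 20 kept 1 library apart on each side, where the highest other count was 0 in each of these comparisons, but 20 are too few for a share under 0.05. Of 100 splits, 1 gave as many genes for the trend (4013, highest other 1263) and for any dose (3255, highest other 1953), which argues against chance. With 1 library apart kept in each group, 1 of 100 splits gave as many for each (highest other 376 and 1). At 0.03 mg/kg-day edgeR called 0 genes (565 at an unadjusted p under 0.05, 1 by limma-voom, 11 by DESeq2), so all 35 splits had to give as many and their count says nothing.

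For the process lists at 0.3 mg/kg-day, 1 of 35 splits gave as many as the 16 called (highest other 14). Over all splits this argues against chance, though by a small margin and without adjustment for the number of tests. In the 20 splits that kept 1 library apart on each side the highest other was also 14, but 20 are too few for a share under 0.05. Chance is not excluded at 0.03 mg/kg-day, where 13 splits gave 7 or more (highest other 13). At 3.0 mg/kg-day 5 splits gave 21 or more (highest other 23) and at 6.0 mg/kg-day 4 gave 23 or more (highest other 24), so this count does not exclude chance there. Apart from the real split, all of these kept 3 treated mice together and so held much of the dose contrast. The 18 splits with 2 treated mice on each side gave at most 14 and 7 lists, but alone they are too few for a share under 0.05. For the marker lists at 6.0 mg/kg-day 27 splits gave 2 or more (highest other 5), of them 15 with 2 treated mice on each side, so chance is not excluded. For the marker list called at 0.03 mg/kg-day, 4 of the 18 splits with 2 treated mice on each side and 6 of 16 other splits gave 1 or more, which leaves chance open too.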

How the results depend on the processing

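The term for the 5 libraries apart and the fit without them were chosen after the data were seen, and the other alternatives before. Where a count moved, the cause was not tested. Summed symbols were not run, since only 2 date names, and no gene symbol, occurred more than once. Single lanes and a pseudocount were not run, since the table has 1 column per library and holds counts. No paired analysis was run, because the groups share no replicate numbers in the labels. A block on the place within the group was not run.

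The genes at 0.03 mg/kg-day, 0 by edgeR (565 at an unadjusted p under 0.05), were 1 with RLE factors, 1 by limma-voom, 11 by DESeq2, 13 with the term for the libraries apart and 2 without those libraries. At 0.3 mg/kg-day the 44 genes became 185 by DESeq2, 306 with the term and 158 without those libraries. At 3.0 mg/kg-day the 701 genes of 15197 tested became 409 of 7557 at a mean of 10 CPM or more, and 1393 with the term. At 6.0 mg/kg-day the 3405 genes became 1725 with the 2 groups alone, 5639 with the term and 5228 without those libraries. For 6.0 against 3.0 mg/kg-day the 318 genes became 0 with the 2 groups alone by edgeR (1575 at an unadjusted p under 0.05), 649 by DESeq2, 1400 with the term and 1476 without those libraries. The trend count went from 4013 of 15197 genes tested to 2660 of 7557 at a mean of 10 CPM or more. Any dose rose from 3255 to 6035 with the term and 5523 without those libraries.

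With an estimated inter-gene correlation the process lists called fell from 7, 16, 21 and 23 to 0, 4, 11 and 15 in order of dose. The marker lists called at 6.0 mg/kg-day fell from 2 to 1 with an estimated correlation, at a mean of 10 CPM or more, with the sequencing sample number as covariate, with the 2 groups alone, with the term and without the libraries apart. With no low-count filter 3 of 10 were called, 1 of them up.

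With each mouse left out, the genes at 0.03 mg/kg-day ran from 0 to 1, the latter without library 4, and the lists from 7 to 9. At 0.3 mg/kg-day the genes ran from 12 to 51, with 14, 13 and 24 without libraries 1, 2 and 3, 17, 16 and 12 without libraries 14, 15 and 16, and 51 without library 4. The lists there ran from 14 to 18. At 3.0 mg/kg-day the genes ran from 451 (without library 20) to 681 and the lists from 19 to 21. At 6.0 mg/kg-day the genes ran from 2346 (without library 22) to 4653 (without library 23), the lists from 22 to 24 and the marker lists from 1 to 2, with 1 without libraries 1, 2, 22, 23 or 24. For 6.0 against 3.0 mg/kg-day they ran from 110 (without library 17) to 969 (without library 23), with 133 without library 18 and 126 without library 22. The trend ran from 2825 to 4376 genes and any dose from 2334 to 4260.

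Of the genes named in the text at 6.0 mg/kg-day, the ones whose direction reversed had not passed at that dose. Saa1 (-0.015) was at 0.007 with RLE factors, 0.008 at a mean of 10 CPM or more, 0.087 with the sequencing sample number, 0.065 by limma-voom, 0.009 by DESeq2 and 0.004 with the term, and ran from -0.165 to 0.369, including 0.042 without library 22 and 0.076 without library 24. Ccnd1 (-0.042) ran from -0.276 to 0.131, including 0.071 without library 3 and 0.059 without library 21. Cd3e (1.783) ran from -0.267 without library 22 to 2.133.

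The 164 results of named genes were compared by call and direction, and not by size. Both were the same in 163 with RLE factors, 157 with total counts only, 161 with no low-count filter and 158 with the sequencing sample number. They were also the same in 158 by limma-voom, 159 with the term and 161 without the libraries apart. At a mean of 10 CPM or more they were the same in 145 of 147, and with the 2 groups alone in 137 of 153. By DESeq2 they were the same in 161 of 163, and for the trend on dose or its log10 in 10 of 10. Over 1432 values with a mouse left out, 87 lost their call, 8 gained a call and 7 reversed in direction.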

Other observations

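In this part the term for the libraries apart, the fit without them, the test of a shared place, and Sult1e1 and Sult2a1 were chosen after the results were seen.

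Vnn1 and Cdkn1a passed in opposite directions at 0.3 and 6.0 mg/kg-day, but not at 0.3 mg/kg-day without the libraries apart (adjusted p = 0.0539 and 0.0534). Their changes in that fit were -1.11 and -1.62, and with the term for those libraries both passed at 0.3 mg/kg-day. Vnn1 means were 38.0, 19.0, 16.4, 52.5 and 134.9 CPM in order of dose. Cdkn1a went from 2.02 CPM in controls to 0.668 CPM at 0.3 and 7.98 CPM at 6.0 mg/kg-day. The list of other PPARA targets was called down at 0.3 mg/kg-day (median -0.13, adjusted p = 0.00589, 0.364 with an estimated correlation) and up at 6.0 mg/kg-day (median 0.64). With a mouse left out, both calls at 0.3 mg/kg-day were lost in 7 of 8 fits, while the changes stayed within -1.35 to -1.09 for Vnn1 and -1.73 to -1.36 for Cdkn1a. A course that turns with dose stays a hypothesis.

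Genes of the female-biased list went both ways at 6.0 mg/kg-day. While 15 of its 23 members fell, the sulfotransferase genes Sult1e1 and Sult2a1 rose by 2.37 and 2.58. Saa1, an acute phase gene, had group means of 14.1, 12.6, 50.6, 50.8 and 14.0 CPM in order of dose, with an SD of 30.4 at 0.3 and 50.1 at 3.0 mg/kg-day, and did not pass at 6.0 mg/kg-day.

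The libraries apart all held place 3 in their groups, with a chance of 0.0039 for a shared place. Their sequencing sample numbers were 13, 3, 11, 8 and 1, which gives no order on the run. The shared place was noticed in the data. It may point to a step done by place in the group, and transcript length (rho 0.48) is the measured feature of the shift.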
